A study of Homo sapiens with 54 samples.

How the data were processed

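ATAC-seq libraries of MDA-MB-231 and PC3 cells came from untreated cells and from cells that survived cisplatin, taken 1 and 10 days after its removal. Per the labels, each of the 6 groups had 3 biological replicates, each split into 3 experimental replicates before tagmentation. The submitters' processing notes name FastQC 0.12.1, Bowtie2 2.3.5.1, Picard, SAMtools 1.6, R 4.4.1 and Genrich 0.6.2 and the builds hg38 and GRCh38. The deposited files are 18 peak lists without headers, 1 per biological replicate; how the experimental replicates were combined is not given in the sources used here. Lists were matched to groups by the cell line, state and replicate number in their names, which match sample titles. All lists were used.

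Each list has 10 columns in the narrowPeak layout. The deposited column 7 is a score, read here as the peak area from its values, with a lowest value of 200. Column 8 holds the deposited -log10 p-value of each peak, with a lowest value of 2.52. Areas are the authors' values and were used only to rank peaks within a list. The lists hold no read counts, so depth is unknown, and differences between lists include any difference in depth. A stretch of chromosome 6 from 28489230 to 31143323 (66 protein-coding genes) had no peak in any list. Chromosomes 1 to 22 and X were analysed.

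The number of peaks, covered length, median width and shares by position were computed per list. Gene positions came from a RefSeq table of GRCh38.p14 with 19970 protein-coding genes, which gives no strand, exons or sequence. A window of 1 kb at either gene end therefore replaced the planned start-site window. Gene-poor windows are the 731 of 2878 windows of 1 Mb with at most 1 protein-coding gene. Chromosomes were split into 41 arms at the peak-free gap of at least 1 Mb nearest the centromere. Group values were compared by two-sided exact permutation tests, with 20 relabellings per line (smallest p 0.1) and 400 over both lines (smallest p 0.005).

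Peaks were merged into 152338 regions in MDA-MB-231, 194852 in PC3 and 232138 over both lines, and a list had a region where a peak overlapped it by at least 1 bp. For each gene, covered length in the body and 10 kb on each side was scaled to the mean total covered length of the lists. Genes with at least 500 bp in at least 3 lists were kept (16813), and log2(length + 500 bp) was fitted with limma 3.58.1 in R 4.3.3, with all groups in 1 fit, a trend in the variance, 12 residual degrees of freedom and Benjamini-Hochberg adjustment at 0.05. Neighbouring and overlapping genes share peaks, so their values are not independent.

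The 24 gene lists (557 entries, 1 matched through an older symbol) cover p53 targets, Fanconi and homologous recombination repair, nucleotide excision and mismatch repair, G1/S and replication, mitosis, secretory inflammatory factors, interferon-stimulated and immediate early genes, mesenchymal and epithelial genes, oxidative stress, drug transporters, hypoxia, lipid synthesis, lysosome and autophagy, nuclear lamina, chromatin modifiers, apoptosis, stemness, HOX, neuronal, haematopoietic, endothelial and housekeeping genes. Lists were tested with camera in limma at a preset correlation of 0.01, and again with an estimated one. Gene lists, the planned tests and alternatives and the rule for named genes were set before the data were examined. Chosen after were the matched random lists, the splits for counts of genes, the tests of list length, of the secretory list at equal list length and of gene density on 18q, and 2 alternatives named below. For each treated group against control, the rule took up to 10 genes with the largest rise and 10 with the largest fall among called genes with non-overlapping groups, up to 4 members of each list by p, and up to 10 genes at the widest regions gained and lost in both lines. The text gives a selection of these.

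The fit was tested on simulated data with 200 changed genes for MDA-MB-231 at day 1: 51.0% were recovered at a log2 change of 0.5, 96.5% at 1 and 100% at 2. False calls made up 2.9%, 3.0% and 7.0% of the calls, the last above the threshold of 0.05. In 400 simulated comparisons without a difference the exact test over both lines fell under 0.05 in 4.75%. Agreement between times was set beside 20 simulations of unchanged groups. Replicate numbers are shared between groups. Deviations from the group means correlated above 0.1 for every same-numbered pair of MDA-MB-231 day 1 and control (from 0.195 to 0.389), MDA-MB-231 day 10 and day 1 (from 0.198 to 0.418) and PC3 day 10 and day 1 (from 0.13 to 0.345), so the numbers were taken to pair the lists in those comparisons only. This pairing comes from the data and not from the labels. In MDA-MB-231, pairing in both of those comparisons would imply it for day 10 and control too. Correlations there were 0.33, 0.133 and 0.0564, so that case is unsettled.

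Alternatives were the 50000 highest-area peaks of each list, the upper 50% of each list by area, other overlap, summit and presence rules, a gene-end window of 2.5 kb, pseudocounts of 100 and 2000 bp, no filter, no scaling, median-of-ratios scaling, each line alone, the replicate block and each list left out. Gene bodies without flanks and values relative to the chromosome arm were chosen after seeing the data. Summaries used Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and figures matplotlib 3.10.9.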

Results

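Open chromatin was mapped by ATAC-seq, which uses a transposase to cut and tag accessible DNA, in MDA-MB-231, a triple-negative breast cancer line, and PC3, a prostate cancer line derived from a bone metastasis. Cells were left untreated, or survived cisplatin, a platinum drug that crosslinks DNA, and were taken 1 or 10 days after the drug was removed. Each of the 6 groups had 3 biological replicates, each split in 3, which gives 54 sequenced samples. The values analysed are 18 peak lists, 1 per biological replicate, so n = 3 lists per group. The lists hold no read counts and their depth is unknown. They held from 82392 to 165535 peaks. Pairs of lists of the same group shared from 63.9% to 83.2% of their joint covered length.

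The first comparison asks how the number and position of accessible sites differed between survivors and untreated cells. Both lines carried more peaks after cisplatin at both times. In MDA-MB-231 the number was 89564 ± 8381 (SD, n = 3) in control cells, 118115 ± 16585 at day 1 and 117149 ± 11836 at day 10. In PC3 it was 111646 ± 4424, 138253 ± 25044 and 150115 ± 15834. The share of peaks within 1 kb of either end of a protein-coding gene was lower in survivors, at 14.9 ± 0.270% in control, 12.9 ± 0.746% at day 1 and 12.4 ± 1.04% at day 10 in MDA-MB-231, and 11.7 ± 0.262%, 10.7 ± 0.713% and 10.2 ± 0.716% in PC3. The share of intergenic peaks was higher, at 39.6 ± 0.157%, 42.5 ± 0.390% and 44.3 ± 0.799% in MDA-MB-231, and 45.3 ± 0.341%, 47.0 ± 0.173% and 47.9 ± 0.681% in PC3.

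Over both lines the peak number rose by 0.34 log2 at day 1 and 0.40 log2 at day 10 (exact permutation p = 0.005 and 0.005, where 0.005 is the smallest the test can give). Gene-end shares differed by -1.51 and -1.96 percentage points (exact permutation p = 0.005 and 0.005). Intergenic shares rose by 2.29 and 3.65 points (exact permutation p = 0.005 and 0.005), and day 10 exceeded day 1 by 1.36 points (exact permutation p = 0.01). With the 50000 highest-area peaks of each list the rises were smaller. Shares were then 36.2%, 37.1% and 38.5% in MDA-MB-231, where day 1 and control lists overlapped, and 40.3%, 41.7% and 42.8% in PC3. Windows of 1 Mb with at most 1 protein-coding gene held 0.746 points more of the covered length at day 1 (exact permutation p = 0.025) and 1.24 points more at day 10 (exact permutation p = 0.01). By line this share was 4.43 ± 0.0945%, 5.62 ± 0.1995% and 6.09 ± 0.462% in MDA-MB-231 in control, at day 1 and at day 10, and 9.17 ± 0.471%, 9.46 ± 0.358% and 9.98 ± 0.690% in PC3, where treated and control lists overlapped at both times. The day 1 difference did not pass without PC3 day 1 replicate 1 (0.646 points, exact permutation p = 0.05). Covered length rose by 0.22 log2 at day 1 (exact permutation p = 0.015), and its difference of 0.12 at day 10 did not pass (exact permutation p = 0.205). The lines differed here, with 65.2 ± 2.65, 79.5 ± 2.60 and 77.6 ± 6.86 Mb in PC3, where the lists of both times lay above those of control, and 63.7 ± 8.49, 70.7 ± 4.02 and 63.0 ± 6.98 Mb in MDA-MB-231, where lists overlapped. Median peak width differed by -0.10 log2 at day 1 and -0.26 at day 10 and did not pass (exact permutation p = 0.565 and 0.145). Leaving out 1 of the lists changed the day 10 call. By replicate number, widths in MDA-MB-231 were 365, 592 and 587 bp in control and 350, 522 and 459 bp at day 1. In PC3 they were 435, 455 and 429 bp, and 346, 541 and 455 bp. With the 50000 highest-area peaks of each list, the day 1 differences in covered length (0.00 log2, exact permutation p = 0.96), gene-end share (-0.289 points, p = 0.345) and gene-poor share (-0.0666 points, p = 0.78) did not pass, nor did the gene-poor share at day 10 (0.214 points, p = 0.315). The gene-end share of day 10 against day 1 passed only with those lists (-0.965 points, exact permutation p = 0.045; -0.458 points, p = 0.32 with whole lists). By line these lists had gene-end shares of 22.1% (from 21.7 to 22.9), 22.0% (from 21.4 to 22.8) and 21.7% (from 21.2 to 22.5) in MDA-MB-231, which overlapped in every comparison, and 20.1% (from 19.8 to 20.3), 19.6% (from 18.9 to 20.1) and 18.0% (from 17.9 to 18.1) in PC3, where only day 10 lay apart.

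**Figure D1:**
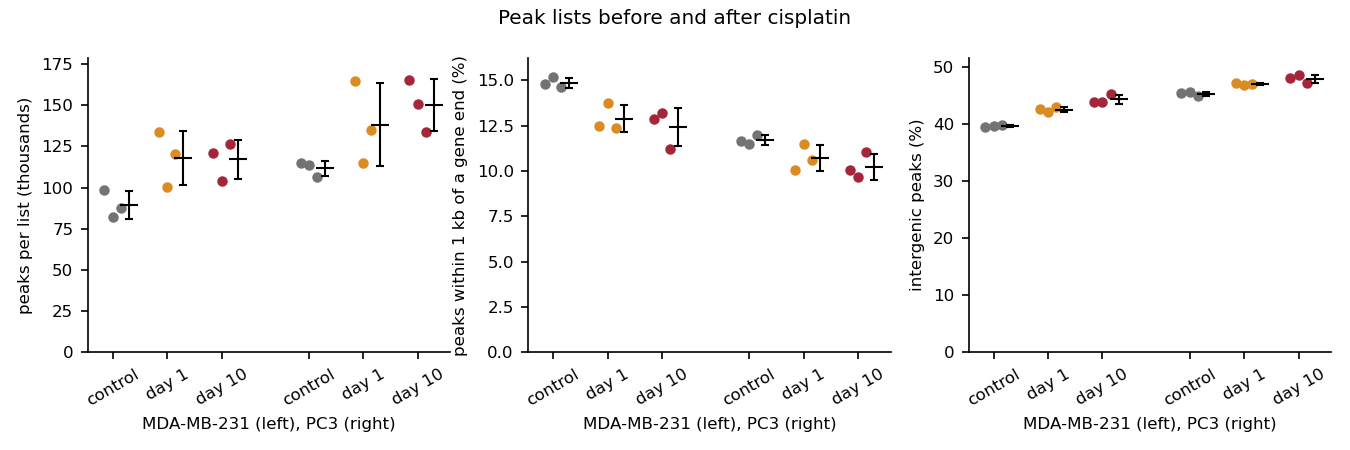
Number of peaks (in units of 1000), share of peaks within 1 kb of a gene end (%) and share of intergenic peaks (%) in each list, by line and state; points are the 3 lists of a group and the bars beside them the mean ± SD. The control lists of MDA-MB-231 hold from 82392 to 98777 peaks and those at day 1 from 100564 to 133526.

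A region was taken as gained when all 3 treated lists and none of the 3 control lists had a peak in it, and as lost in the opposite case. MDA-MB-231 gained 11970 regions and lost 1042 at day 1, and gained 15295 and lost 1384 at day 10. PC3 gained 8349 and lost 794 at day 1, and gained 20244 and lost 2583 at day 10. Simulated unchanged groups gave 682 gained and 688 lost in MDA-MB-231, and 895 and 898 in PC3. The simulation drew all lists of a line alike, from presence over treated and control lists together. It leaves out that treated lists were longer on average, so it cannot decide whether the 794 lost in PC3 at day 1 exceed chance. Leaving out a list loosens the rule, so counts of regions can then only stay or rise. With 1 list left out, gained regions reached 21034 (without day 1 replicate 2) in MDA-MB-231 and 17331 (without day 1 replicate 2) in PC3 at day 1. Lost regions reached 1895 and 3145 (without day 10 replicate 3) in MDA-MB-231 at day 1 and day 10, and 1792 and 4334 in PC3. Of the gained regions of MDA-MB-231 5.95% at day 1 and 3.13% at day 10 touched a gene end, against 11.7% of all regions of the line, and in PC3 6.35% and 4.23% did, against 9.39%. Of the lost regions 12.1% and 12.1% did in MDA-MB-231, and 5.16% and 8.36% in PC3, so at day 1 in PC3 a low share was not particular to gains. Lists of 50000 peaks gave 2880 gained and 2323 lost regions in MDA-MB-231 at day 1, 3843 and 2696 at day 10, 1975 and 1805 in PC3 at day 1, and 4199 and 4221 at day 10; an equal number of peaks per list holds gains and losses near balance by construction.

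Of the regions gained at day 1, 54.9% in MDA-MB-231 and 69.2% in PC3 were gained at day 10 too. Simulated unchanged groups sharing 1 set of controls gave 16.2% and 16.8%. This simulation too leaves out that treated lists were longer on average. It cannot decide how far the shared gains go beyond list length. Regions gained at both times numbered 6574 and 5777, where independent gains would give 1202 and 867. Regions lost at both times numbered 480 and 616 (46.1% and 77.6% of those lost at day 1; simulated 18.1% and 17.7%). Part of the excess may come from the shared controls, since 3 control lists cannot be divided with 2 or more each. Between day 1 and day 10, MDA-MB-231 gained 3517 regions and lost 3799, and PC3 gained 4962 and lost 2089. With lists of 50000 peaks these were 1672 and 1644, and 1518 and 1140. In MDA-MB-231 the balance turned with the list left out, from 3552 gained and 8000 lost without day 1 replicate 2 to 6691 and 3913 without day 10 replicate 2, and in PC3 gains reached 10513 (without day 10 replicate 3) and losses 3989 (without day 1 replicate 2). A rise of either count with a list left out is fixed by the looser rule, while their balance is not.

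Some regions changed in both lines. At day 1, 1016 regions were gained in both, where independence would give 412, and 27 were lost (independent 3.35). Regions gained in 1 line and lost in the other numbered 4 (independent 74). Independence takes every region as equally likely to change and leaves out peak strength and longer treated lists. Whether the lines shared a response is thus undecided. At day 10, 2673 were gained in both (independent 1295) and 46 were lost (independent 14.5). Opposite changes then numbered 35 (independent 278). With 50000 peaks per list, 169 were gained in both (independent 59) and 93 lost (independent 43) at day 1. At day 10 these were 433 (independent 167) and 173 (independent 116). With 1 list left out, which can only keep or raise these counts, shared gains at day 1 reached 1608 (independent 859). Shared losses reached 54 (independent 7.6) at day 1 and 164 (independent 33) at day 10. Of the shared gains at day 1, 85 touched a gene end. The widest (chromosome 1, 201419196 to 201423015) lies at an end of TNNI1, which encodes a slow-muscle troponin subunit. Others lie at AANAT and RHBDF2 (chromosome 17, 76467368 to 76470717), ULK4, PCSK7, NISCH and STAB1, and NUP62. ISOC2 was at the only shared loss at a gene end (chromosome 19, 55452967 to 55453304). At day 10, 116 shared gains touched a gene end. The widest (chromosome 5, 132076179 to 132078940) lies beside CSF2, the gene of the cytokine GM-CSF. It was followed by regions at IFI35 and VAT1 (chromosome 17, 43013278 to 43015454), RBCK1, MOGAT2, MADD and MYBPC3, and CBL. The 7 shared losses at gene ends were at SYNGR1, COCH, MADCAM1, MEF2B, RAPGEF4, ISOC2 and ZBTB40. Strand is not used, so an end can be the start or finish of a gene.

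**Figure D2:**
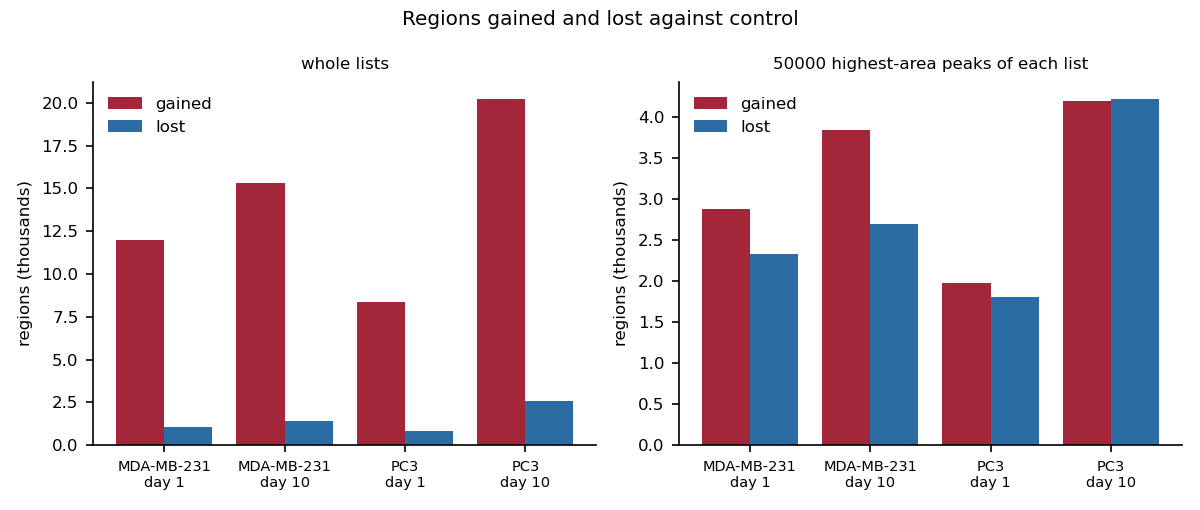
Regions gained (red) and lost (blue) against control, in units of 1000, for each line and time, from whole lists (left) and from the 50000 highest-area peaks of each list (right). PC3 at day 10 gained 20244 and lost 2583 regions with whole lists, and 4199 and 4221 with lists of equal length.

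Accessibility per gene is the scaled covered length in the gene body and 10 kb on each side, compared on the log2(length + 500 bp) scale, which understates changes of genes with little covered length. Changes also shift with the length of this window and the control level, as matched random lists below show. Named genes are not corrected for this. In MDA-MB-231 at day 1, CACNA1B, which encodes a neuronal calcium channel (chromosome 9, 137877782 to 138124619), rose from 0.376 ± 0.255 kb (SD, n = 3) to 7.20 ± 3.38 kb, a log2 change of 3.07 (SE 0.32). SLC22A12, the urate transporter gene, rose by 2.48 log2, DNAH9, an axonemal dynein gene, by 2.44, and DPP6, which encodes a potassium channel partner, by 2.44. PTGDS, a prostaglandin D synthase gene (-1.66), SMAD4, the shared signal mediator of the TGF-beta family (-1.49), PABPC4 (-1.46), NUDT14 (-1.33), NAT8L, which makes N-acetylaspartate (-1.29), and TBC1D10C (-1.24) fell. The limma adjusted p of these genes ran from 1.71e-07 for DNAH9 to 0.00116 for TBC1D10C. Of 115 pairs of a named gene and a comparison measured with 50000 peaks per list, 58 kept direction and side of the threshold, 55 direction only and 2 reversed.

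Among the gene lists at day 1 in MDA-MB-231, neuronal and neuroendocrine genes were called as higher, with 7 of 23 higher and 2 lower (8 and 3 adjusted over the list alone, 7 and 1 with no scaling, 7 and 1 with median-of-ratios scaling). Examples were NCAM1, a neural adhesion molecule (log2 1.97), CNTNAP2 (1.46) and NRXN3, a presynaptic adhesion gene (1.26), while TUBB3, a neuronal tubulin gene, fell (-0.51). The list had adjusted p = 0.0473, and 0.29 with an estimated correlation, 0.376 with 50000 peaks per list, 0.113 with no scaling and 0.0937 relative to the chromosome arm. Hypoxia response genes were called as lower, with 0 of 22 higher and 8 lower (0 and 9 adjusted over the list alone, 0 and 0 with no scaling, 1 and 2 with median-of-ratios scaling), among them STC2 (-0.45), ADM, which encodes adrenomedullin (-0.38), and LOXL2 (-0.37). That list had adjusted p = 0.0473, and 0.29 with an estimated correlation, 0.543 with 50000 peaks per list, 0.121 with no scaling and 0.0922 relative to the chromosome arm. Housekeeping genes, a control list, were called as lower too, with 0 of 18 higher and 6 lower (0 and 7 adjusted over the list alone, 0 and 0 with no scaling, 0 and 3 with median-of-ratios scaling), such as TUBA1B (-0.41) and ATP5F1B (-0.40). They had adjusted p = 0.0473, and 0.544 with an estimated correlation, 0.66 with 50000 peaks per list, 0.113 with no scaling and 0.0922 relative to the chromosome arm. The p53 targets had 0 of 24 higher and 3 lower (0 and 3 adjusted over the list alone, 0 and 0 with no scaling, 1 and 0 with median-of-ratios scaling) and were not called (adjusted p = 0.562), and their median of -0.11 became 0.02 with no scaling. CDKN1A, the cell cycle inhibitor p21 (-0.36), and BBC3, the pro-apoptotic PUMA (-0.31), fell. MMP10, a matrix metalloproteinase gene, rose by 1.40 log2 and FANCI, a Fanconi anaemia gene, by 0.88. KRT5, a basal keratin gene, was listed at 0 in the 3 control lists and had 0.825 ± 0.420 kb at day 1. The 50000-peak lists gave -0.28 for FANCI. Haematopoietic genes, markers of another cell type, had 5 of 18 higher and 3 lower (5 and 0 with no scaling, 5 and 0 with median-of-ratios scaling, with adjusted p = 0.301, median -0.07, which became 0.06 with no scaling, mean 0.27). With no scaling ADM, ATP5F1B, BBC3, CDKN1A, LOXL2, STC2 and TUBA1B did not pass. With median-of-ratios scaling BBC3, CDKN1A and LOXL2 did not pass. With 50000 peaks per list ADM, ATP5F1B, BBC3, CDKN1A, CNTNAP2, KRT5, MMP10, NCAM1, SLC22A12, STC2, TUBA1B and TUBB3 did not pass. Among 10000 random lists matched on window length and control level, a comparison chosen after seeing the data, the medians of the neuronal, hypoxia and housekeeping lists lay at the 82.6, 1.4 and 26.7 percentiles. Random lists matched to the neuronal list had a median of 0.05, and those matched to the housekeeping list -0.17. At day 10 in this line the 2 values were 0.04 and -0.19. Lists not called whose medians lay outside the central 95% of random lists were mitosis and cytokinesis at 0.55 and HOX genes at 1.2. Random genes were drawn singly. Here and below, percentiles are therefore too extreme for lists whose members share peaks, such as neighbouring HOX genes.

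Over all 16813 genes, 1816 were higher and 2605 lower at day 1 in MDA-MB-231 by limma at an adjusted p of 0.05, and 45.6% had non-overlapping groups, where chance gives 10%. The split was 2235 and 956 with median-of-ratios scaling and 1897 and 318 with no scaling, and the median over all genes moved from -0.09 to 0.01 and 0.04. Lists of 50000 peaks gave 648 and 531. With 1 list left out there were as few as 1159 lower without day 1 replicate 3.

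At day 10 in MDA-MB-231, CACNA1B had risen by 3.48 log2 (SE 0.32, n = 3), DRGX, a homeobox gene of sensory neurons, by 3.05, AGBL4 by 2.88, LRFN2 by 2.87 and MACROD2 by 2.77. EPS8L1 (-2.00), NAT8L (-1.65), YJEFN3 (-1.52), SMIM24 (-1.49) and FSD1 (-1.29) fell. Secretory inflammatory genes were called as higher, with 7 of 25 higher and 3 lower (8 and 3 adjusted over the list alone, 7 and 1 with no scaling, 10 and 1 with median-of-ratios scaling). The matrix metalloproteinase genes MMP10 and MMP3 rose by 1.72 and 1.49, and IL1B, the interleukin-1 beta gene, by 1.44. CCL2, a monocyte chemokine gene, was listed at 0 in the 3 control lists and had 0.903 ± 0.117 kb at day 10. The list had adjusted p = 0.036, and 0.125 with an estimated correlation. With the replicate block, whose pairing is unsettled in this comparison, the list did not pass. Neuronal and neuroendocrine genes were called as higher, with 9 of 23 higher and 2 lower (11 and 3 adjusted over the list alone, 8 and 1 with no scaling, 10 and 1 with median-of-ratios scaling), among them NCAM1 (2.42), NRXN3 (1.30), CNTNAP2 (1.09) and GRIN2B, a glutamate receptor subunit gene (0.98). They had adjusted p = 0.0213, and 0.125 with an estimated correlation and 0.326 with 50000 peaks per list. Among the matched random lists the secretory median lay at the 99.99 percentile and the neuronal median at 99.1, and, among lists not called, outside the central 95% were p53 targets at 97.7, Fanconi and homologous recombination repair at 1.03, mitosis and cytokinesis at 1.62, interferon-stimulated genes at 97.8, immediate early and AP-1 factors at 99.95 and HOX genes at 0.01.

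Other lists were not called at day 10 in MDA-MB-231. HOX genes, which pattern the body axis, had 1 of 35 higher and 12 lower (1 and 12 adjusted over the list alone, 1 and 6 with no scaling, 1 and 6 with median-of-ratios scaling) and an adjusted p of 0.102; HOXB7 went from 2.05 ± 0.514 to 0.839 ± 0.594 kb, HOXB8 changed by -0.92 and HOXC9 by -0.44. Nuclear lamina and envelope genes had 1 of 22 higher and 7 lower (1 and 8 adjusted over the list alone, 1 and 1 with no scaling, 1 and 2 with median-of-ratios scaling) and an adjusted p of 0.243, with the lamin genes LMNA at -0.39 and LMNB1 at -0.42 (0.10 with 50000 peaks per list) and the nucleoporin gene NUP210 at 1.16. Hypoxia response genes had 0 of 22 higher and 8 lower (0 and 10 adjusted over the list alone, 0 and 3 with no scaling, 1 and 3 with median-of-ratios scaling) and an adjusted p of 0.074, with STC2 at -0.54 and LOXL2 at -0.42. Fanconi and recombination genes had 0 of 22 higher and 3 lower (0 and 3 adjusted over the list alone, 0 and 1 with no scaling, 0 and 1 with median-of-ratios scaling) and an adjusted p of 0.102, with FANCL at -0.51 and PALB2 at -0.36. Chromatin modifiers had 0 of 27 higher and 5 lower (0 and 5 adjusted over the list alone, 0 and 2 with no scaling, 0 and 2 with median-of-ratios scaling) and an adjusted p of 0.151, with the demethylase genes KDM5A at -0.65 and TET1 at -0.44. Endothelial genes, markers of another cell type, had 5 of 14 higher and 3 lower (6 and 4 adjusted over the list alone, 3 and 3 with no scaling, 5 and 3 with median-of-ratios scaling) and an adjusted p of 0.194, with ERG at 2.42, FLT1 at 1.42 and TIE1 at 1.42. Haematopoietic genes had 6 of 18 higher and 1 lower (6 and 1 adjusted over the list alone, 6 and 0 with no scaling, 6 and 0 with median-of-ratios scaling) and an adjusted p of 0.116, with a median of -0.12 and a mean of 0.36. CCND1, the cyclin D1 gene, fell (-0.66) and SPATA18, a p53 target, rose (0.74). Housekeeping genes had 0 of 18 higher and 5 lower (0 and 5 adjusted over the list alone, 0 and 2 with no scaling, 0 and 1 with median-of-ratios scaling) and an adjusted p of 0.102, with TUBA1B at -0.45. With no scaling LMNA and PALB2 did not pass. With median-of-ratios scaling PALB2 did not pass. With 50000 peaks per list CCND1, CNTNAP2, EPS8L1, FANCL, GRIN2B, HOXB7, HOXB8, HOXC9, KDM5A, LMNA, LOXL2, LRFN2, PALB2, SMIM24, SPATA18, STC2, TET1 and TUBA1B did not pass.

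Over all 16813 genes, 1841 were higher and 2809 lower at day 10 in MDA-MB-231 by limma at an adjusted p of 0.05, and 46.5% had non-overlapping groups, where chance gives 10%. The split was 2175 and 963 with median-of-ratios scaling and 1458 and 1192 with no scaling, and the median over all genes moved from -0.11 to 0.00 and -0.11. Lists of 50000 peaks gave 745 and 553. With 1 list left out there were as few as 1736 lower without control replicate 3.

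In PC3 at day 1, IL18BP, which encodes the interleukin-18 binding protein, rose by 2.65 log2 (SE 0.32, n = 3), CST7 by 2.62, FLT4, a lymphatic growth factor receptor gene, by 2.41, GPR25 by 2.37 and NCAM1 by 2.01. ZDHHC2, a palmitoyltransferase gene (-1.52), FGF2, a fibroblast growth factor gene (-1.37), SMAD7, an inhibitor of TGF-beta signalling (-1.03), and TLE1 (-1.02) fell, and TJP1, a tight junction gene, fell from 1.08 ± 0.0882 to 0.288 ± 0.0116 kb. Of the 24 lists only neuronal and neuroendocrine genes were called, as higher, with 2 of 23 higher and 0 lower (2 and 0 adjusted over the list alone, 7 and 0 with no scaling, 2 and 0 with median-of-ratios scaling), NRXN3 at 0.38 among them. The list had adjusted p = 0.026, and 0.171 with an estimated correlation, 0.488 with 50000 peaks per list, 0.112 with no scaling and 0.0761 relative to the chromosome arm, and its median lay at the 99.9 percentile of the matched random lists. Lists not called but outside the central 95% were secretory inflammatory factors at 99.6, hypoxia response at 1.44, nuclear lamina and envelope at 0.19 and stemness-associated factors at 97.9. Hypoxia response genes had 0 of 22 higher and 4 lower (0 and 11 adjusted over the list alone, 1 and 0 with no scaling, 0 and 2 with median-of-ratios scaling) and an adjusted p of 0.109, and their median of -0.18 became 0.07 with no scaling; P4HA1 (-0.54), KDM3A (-0.47) and ADM (-0.29) fell. BCL2L1, the gene of the survival factor BCL-XL, rose by 0.52, ABCB1, a drug efflux pump gene, by 0.64 and XPC, a DNA damage sensor gene, by 0.61. The Polycomb genes BMI1 (-0.76) and SUZ12 (-0.58) and CDKN1A (-0.28) fell. With no scaling ADM, CDKN1A, KDM3A and P4HA1 did not pass. With median-of-ratios scaling ADM and CDKN1A did not pass. With 50000 peaks per list ABCB1, ADM, CDKN1A, CST7, FGF2, GPR25, IL18BP, KDM3A, NCAM1, NRXN3, P4HA1, SMAD7, TLE1, XPC and ZDHHC2 did not pass. Over all 16813 genes, 1017 were higher and 1221 lower at day 1 in PC3 by limma at an adjusted p of 0.05, and 37.6% had non-overlapping groups, where chance gives 10%. The split was 1469 and 404 with median-of-ratios scaling and 2436 and 32 with no scaling, and the median over all genes moved from -0.07 to 0.00 and 0.16. Lists of 50000 peaks gave 502 and 491. With 1 list left out there were as few as 543 higher and 374 lower without day 1 replicate 3.

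In PC3 at day 10, OPCML, a neural adhesion gene on 11q (chromosome 11, 132414981 to 133532501), rose from 0.463 ± 0.252 to 18.4 ± 5.6 kb, a log2 change of 4.28 (SE 0.20). PTPRT rose by 3.47, TMEM132D by 3.46, DPP6 by 3.43, NCAM1 by 3.31 and COL22A1, a collagen gene, from 2.29 ± 1.16 to 21.4 ± 6.84 kb. ZDHHC2 on 8p fell (-2.08). ATP5F1A, a subunit gene of ATP synthase, and HAUS1, both on 18q, were listed at 0 and 0 in the 3 day 10 lists, from 1.62 ± 0.314 and 1.36 ± 0.134 kb in control. BMI1 on 10p fell (-1.87), and its window overlaps that of COMMD3-BMI1 (-1.72). SAMD11 (-1.66) and FST, the follistatin gene (-1.62), fell as well.

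Secretory inflammatory genes were called as higher at day 10 in PC3, with 5 of 25 higher and 2 lower (5 and 2 adjusted over the list alone, 12 and 1 with no scaling, 14 and 2 with median-of-ratios scaling). CCL2 was listed at 0 in the 3 control lists and had 1.20 ± 0.139 kb at day 10. GDF15, a stress cytokine gene, rose by 0.96 and IGFBP7 by 0.71, and EREG, the epiregulin gene, fell (-0.91). The list had adjusted p = 0.00526, and 0.0537 with an estimated correlation and 0.0976 with 50000 peaks per list. Neuronal and neuroendocrine genes were called as higher, with 5 of 23 higher and 0 lower (5 and 0 adjusted over the list alone), among them RBFOX1, a neuronal splicing factor gene (2.71), NRXN3 (0.86) and SCG3 (0.57). They had adjusted p = 0.00898, and 0.0537 with an estimated correlation and 0.252 with 50000 peaks per list. Endothelial genes, markers of another cell type, were called as higher, with 6 of 14 higher and 1 lower (6 and 1 adjusted over the list alone, 7 and 0 with no scaling, 8 and 0 with median-of-ratios scaling), among them the growth factor receptor genes FLT1 (0.91) and KDR (0.80) and TEK (0.37), while CDH5 fell (-0.34). They had adjusted p = 0.00898, and 0.0537 with an estimated correlation. Chromatin modifiers were called as lower, with 0 of 27 higher and 15 lower (0 and 16 adjusted over the list alone, 0 and 8 with no scaling, 2 and 13 with median-of-ratios scaling), among them HDAC9 (-1.11), KDM6A (-0.78), SUZ12 (-0.68) and SMARCA2 (-0.52). They had adjusted p = 0.017, and 0.197 with an estimated correlation and 0.255 with 50000 peaks per list. Among the matched random lists the secretory, neuronal, endothelial and chromatin modifier medians lay at the 100, 95.3, 99.6 and 0.09 percentiles. Outside the central 95% without being called were interferon-stimulated genes at 99.1, nuclear lamina and envelope at 0.03 and HOX genes at 0.27.

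Further lists in PC3 at day 10 were not called. HOX genes had 1 of 35 higher and 14 lower (1 and 14 adjusted over the list alone, 1 and 6 with no scaling, 1 and 9 with median-of-ratios scaling) and an adjusted p of 0.0885, with HOXA9 at -1.22, HOXB2 at -0.87 and HOXA3 at -0.73. Nuclear lamina and envelope genes had 2 of 22 higher and 13 lower (2 and 13 adjusted over the list alone, 2 and 5 with no scaling, 4 and 11 with median-of-ratios scaling) and an adjusted p of 0.206, with LMNB2 at -0.89 and TMPO at -0.81. Fanconi and recombination genes had 0 of 22 higher and 10 lower (0 and 10 adjusted over the list alone, 0 and 4 with no scaling, 0 and 6 with median-of-ratios scaling) and an adjusted p of 0.0924, with FANCL at -0.67, BRCA1 at -0.61 and BRCA2 at -0.59. Housekeeping genes had 0 of 18 higher and 7 lower (0 and 7 adjusted over the list alone, 0 and 3 with no scaling, 2 and 3 with median-of-ratios scaling) and an adjusted p of 0.237, and their median of -0.21 became 0.01 with no scaling; ACTB changed by -0.99 and SDHA by -0.67. BCL2L1 (0.63) and XPC (0.77) rose, and MDM2 (-0.51) and ADM (-0.50) fell. With no scaling ADM, BRCA2, CDH5, MDM2 and SMARCA2 did not pass. With median-of-ratios scaling CDH5 did not pass. With 50000 peaks per list ACTB, ADM, CDH5, MDM2, SAMD11, SCG3, SMARCA2, TEK, XPC and ZDHHC2 did not pass. Over all 16813 genes, 1983 were higher and 5562 lower at day 10 in PC3 by limma at an adjusted p of 0.05, and 51.2% had non-overlapping groups, where chance gives 10%. The split was 3417 and 2511 with median-of-ratios scaling and 2818 and 1186 with no scaling, and the median over all genes moved from -0.16 to 0.00 and 0.05. Lists of 50000 peaks gave 1391 and 3294.

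On the mean of both lines at day 10, secretory inflammatory genes were called as higher, with 13 of 25 higher and 4 lower (13 and 4 adjusted over the list alone, 13 and 1 with no scaling, 15 and 2 with median-of-ratios scaling, with adjusted p = 0.000922, and 0.0291 with an estimated correlation). Neuronal genes were too, with 8 of 23 higher and 2 lower (7 and 2 adjusted over the list alone, 9 and 1 with no scaling, 11 and 1 with median-of-ratios scaling, with adjusted p = 0.00191, and 0.0337 with an estimated correlation and 0.176 with 50000 peaks per list), and so were endothelial genes, with 6 of 14 higher and 2 lower (6 and 2 adjusted over the list alone, 6 and 1 with no scaling, 9 and 2 with median-of-ratios scaling, with adjusted p = 0.0244, and 0.0921 with an estimated correlation and 0.0605 relative to the chromosome arm). HOX genes were called as lower, with 2 of 35 higher and 23 lower (2 and 27 adjusted over the list alone, 2 and 9 with no scaling, 2 and 11 with median-of-ratios scaling, with adjusted p = 0.0244, and 0.384 with an estimated correlation). Chromatin modifiers were called as lower, with 0 of 27 higher and 17 lower (0 and 17 adjusted over the list alone, with adjusted p = 0.0244, and 0.233 with an estimated correlation and 0.149 with 50000 peaks per list), and Fanconi genes, with 0 of 22 higher and 13 lower (0 and 13 adjusted over the list alone, 0 and 7 with no scaling, 0 and 8 with median-of-ratios scaling, with adjusted p = 0.0432, and 0.276 with an estimated correlation, 0.179 with 50000 peaks per list and 0.0605 relative to the chromosome arm). At day 1 the mean called neuronal genes as higher, with 8 of 23 higher and 3 lower (9 and 3 adjusted over the list alone, 12 and 0 with no scaling, 11 and 0 with median-of-ratios scaling, with adjusted p = 0.0114, and 0.113 with an estimated correlation, 0.2003 with 50000 peaks per list and 0.0669 with no scaling). Hypoxia genes were called as lower at day 1, with 0 of 22 higher and 13 lower (0 and 14 adjusted over the list alone, 0 and 0 with no scaling, 0 and 4 with median-of-ratios scaling, with adjusted p = 0.023, and 0.158 with an estimated correlation, 0.459 with 50000 peaks per list and 0.137 with no scaling), and their median of -0.19 became 0.01 with no scaling. Over all genes the mean had 2213 higher and 4187 lower at day 1, against 3119 and 1531 with median-of-ratios scaling and 3812 and 262 with no scaling. At day 10 it had 2525 and 6640, against 3847 and 2743 and 2750 and 2242.

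The other lists were not called on the mean of both lines at day 10, with adjusted p from 0.0698 to 0.993. Genes higher and lower, with the counts under no scaling and under median-of-ratios scaling in brackets, were 2 and 6 of 24 p53 targets (2 and 2, 5 and 2), 2 and 10 of 19 nucleotide excision and mismatch repair genes (2 and 4, 2 and 5) and 0 and 13 of 22 G1/S and replication genes (0 and 2, 1 and 4). Next were 1 and 15 of 25 mitosis genes (1 and 2, 1 and 4), 7 and 4 of 23 interferon-stimulated genes (8 and 1, 9 and 0) and 1 and 8 of 20 immediate early genes (2 and 1, 2 and 1). Then came 3 and 5 of 22 mesenchymal genes (2 and 1, 3 and 1), 1 and 9 of 22 epithelial genes (2 and 3, 6 and 3) and 1 and 12 of 24 oxidative stress genes (1 and 9, 1 and 9). Further lists had 3 and 8 of 17 drug transporters (3 and 2, 5 and 2), 1 and 13 of 22 hypoxia response genes (1 and 3, 3 and 6) and 3 and 8 of 21 lipid synthesis genes (3 and 3, 6 and 3). Others had 1 and 11 of 19 lysosome and autophagy genes (1 and 2, 2 and 5), 2 and 12 of 22 nuclear lamina genes (3 and 9, 4 and 9) and 3 and 11 of 24 apoptosis regulators (3 and 2, 4 and 2). The last had 4 and 6 of 16 stemness-associated genes (4 and 3, 6 and 3), 6 and 6 of 18 haematopoietic genes (6 and 1, 6 and 2) and 0 and 9 of 18 housekeeping genes (0 and 4, 0 and 5). The medians of p53 targets and interferon-stimulated, immediate early, mesenchymal, epithelial, oxidative stress, lipid synthesis, stemness-associated and haematopoietic genes change sign between the scalings.

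**Figure D3:**
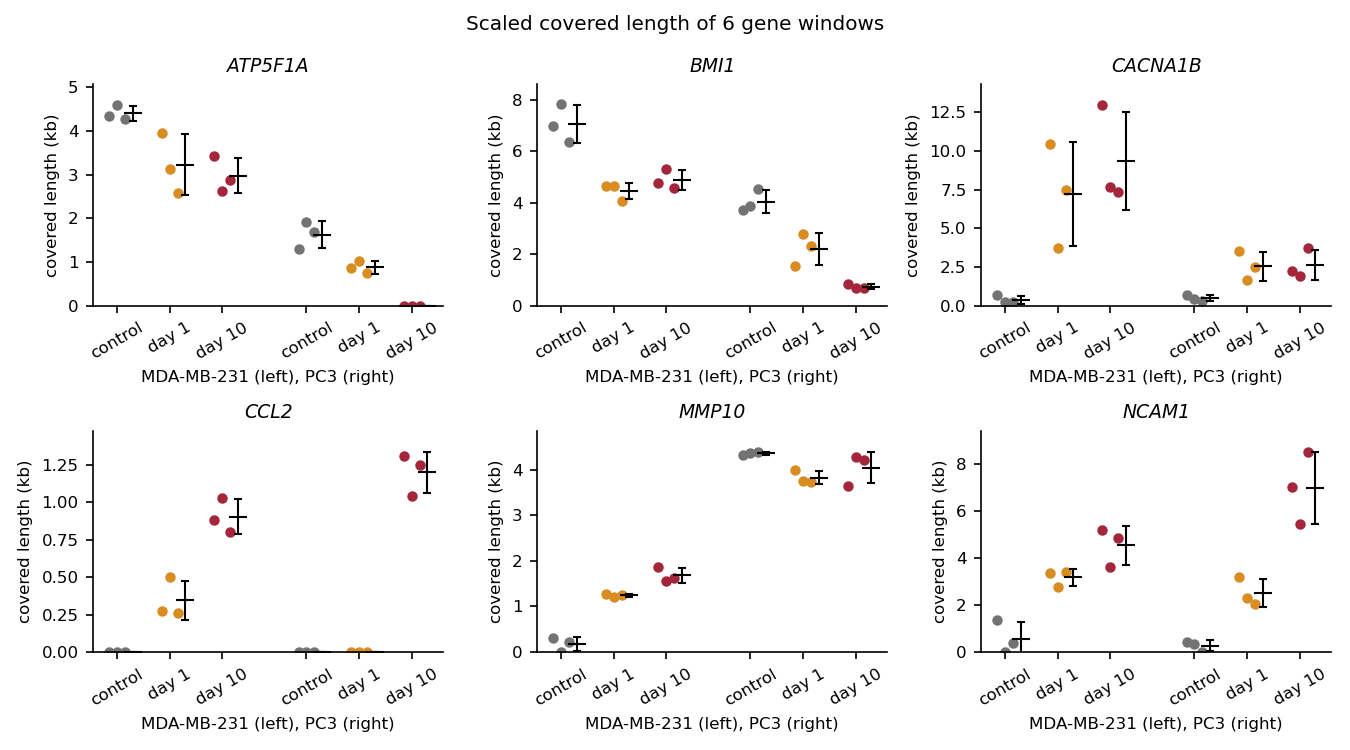
Scaled covered length (kb) within the windows of 6 genes, by line and state; points are the 3 lists of a group, bars the mean ± SD. CCL2 is at 0 in the control lists of both lines, and ATP5F1A is at 0 in the 3 day 10 lists of PC3.

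**Figure D4:**
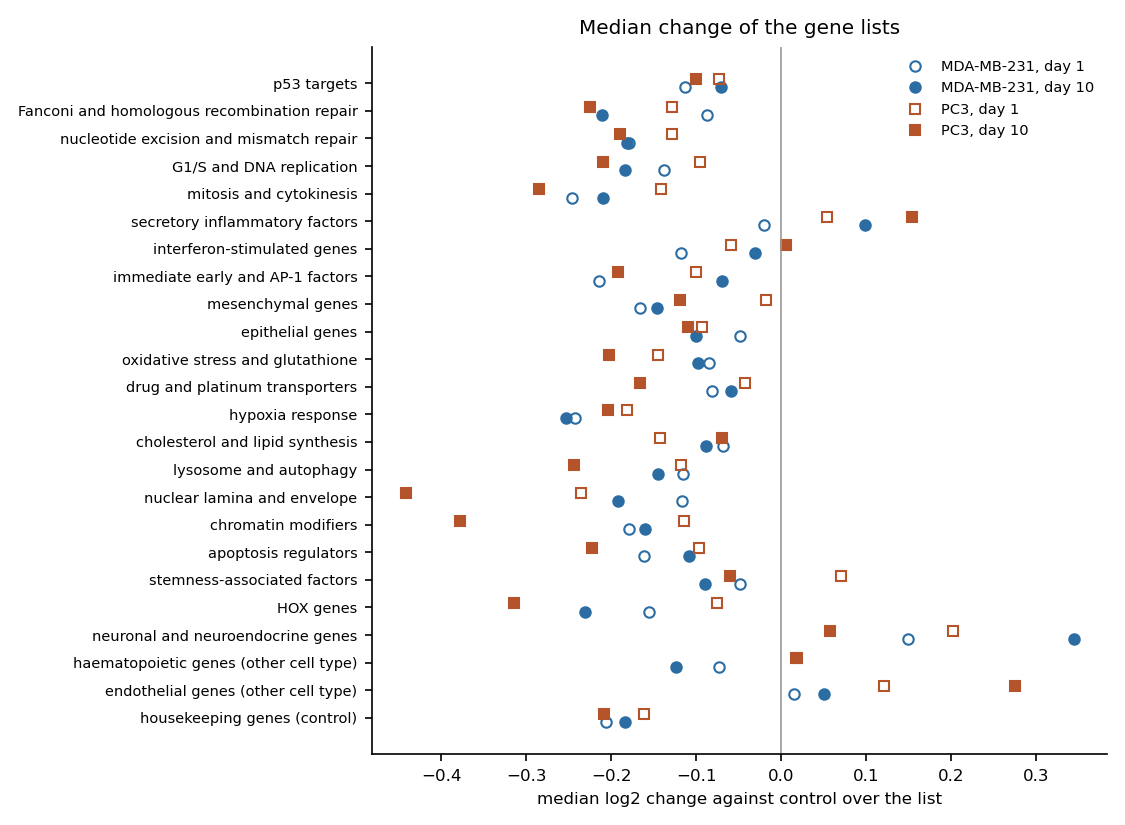
Median log2 change against control of each gene list, for MDA-MB-231 (circles) and PC3 (squares) at day 1 (open) and day 10 (filled). The secretory inflammatory list lies at 0.10 in MDA-MB-231 and 0.15 in PC3 at day 10, and the chromatin modifiers at -0.38 in PC3.

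From day 1 to day 10, on the mean of both lines, secretory inflammatory genes were called as higher, with 6 of 25 higher and 0 lower (8 and 1 adjusted over the list alone, 4 and 1 with no scaling, 7 and 0 with median-of-ratios scaling, with adjusted p = 3.90e-05, and 0.00874 with an estimated correlation), and their median of 0.07 became -0.02 with no scaling. Interferon-stimulated genes were called as higher, with 2 of 23 higher and 0 lower (2 and 0 adjusted over the list alone, 1 and 0 with no scaling, 2 and 0 with median-of-ratios scaling, with adjusted p = 0.0091, and 0.0597 with an estimated correlation and 0.417 with 50000 peaks per list), and their median of 0.05 became -0.05 with no scaling. Endothelial genes were called as higher, with 3 of 14 higher and 0 lower (3 and 0 adjusted over the list alone, with adjusted p = 0.0091, and 0.0597 with an estimated correlation and 0.211 with 50000 peaks per list). HOX genes were called as lower, with 0 of 35 higher and 6 lower (0 and 9 adjusted over the list alone, 0 and 9 with no scaling, 0 and 3 with median-of-ratios scaling, with adjusted p = 0.0068, and 0.398 with an estimated correlation and 0.229 with 50000 peaks per list), as were Fanconi genes, with 0 of 22 higher and 4 lower (0 and 5 adjusted over the list alone, with adjusted p = 0.0454, and 0.342 with an estimated correlation, 0.297 with 50000 peaks per list and 0.0832 relative to the chromosome arm). In MDA-MB-231 no list was called. In PC3 the secretory list had adjusted p = 0.000482, and 0.0223 with an estimated correlation and 0.0956 with 50000 peaks per list, the endothelial list adjusted p = 0.00393, and 0.0293 with an estimated correlation and 0.0956 with 50000 peaks per list, the chromatin modifiers, as lower, adjusted p = 0.0313, and 0.182 with an estimated correlation and 0.463 with 50000 peaks per list, the HOX genes, as lower, adjusted p = 0.041, and 0.618 with an estimated correlation, 0.457 with 50000 peaks per list and 0.0944 relative to the chromosome arm, and the interferon-stimulated genes adjusted p = 0.0381, and 0.137 with an estimated correlation and 0.544 with 50000 peaks per list. MDA-MB-231 had 357 genes higher and 544 lower, or 542 and 794 with the replicate number as a block. PC3 had 370 and 926, and the mean 515 and 1013. With median-of-ratios scaling PC3 had 650 and 510 and the mean 723 and 612. With no scaling MDA-MB-231 had 152 and 819, PC3 215 and 608 and the mean 292 and 1751, and the median over all genes in MDA-MB-231 moved from 0.00 to -0.13. With 1 list left out there were as few as 185 higher without day 1 replicate 2 and 225 lower without day 1 replicate 3 in MDA-MB-231, 185 higher and 323 lower without day 1 replicate 2 in PC3, and 590 lower without PC3 day 1 replicate 2 on the mean.

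Changes at day 1 and day 10 correlated across genes at 0.815 in MDA-MB-231 and 0.812 in PC3, where simulated unchanged groups sharing these controls gave 0.499 in each. Their covariance was 0.132 and 0.105, against 0.00988 and 0.00983 simulated. Genes higher at both times numbered 1260 in MDA-MB-231 and 860 in PC3, where independent calls would share 199 and 120. Genes lower at both times numbered 1411 and 1148, where independent calls would share 435 and 404. Part of this may come from the shared controls. The simulated groups had 1 common mean per gene, so differences in list length are left out there.

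Chromosome arms, not a planned comparison, differed in share of covered length. In PC3 at day 10, arm 18q changed by -0.40 log2, 6q by -0.21, 9p by -0.20, 10p by -0.18, 4p by -0.16 and 8p by -0.15, while 18p (0.30), 20q (0.21), 11q (0.18) and 8q (0.15) were higher, each without overlap of the 3 treated and 3 control lists. With lists of 50000 peaks these were -0.79, -0.50, -0.41, -0.17, -0.39 and -0.39, and 0.41, 0.29, 0.25 and 0.26. Of 41 arms, 9 were higher and 16 lower without overlap, against 4 and 4 at day 1, and 9 and 7 in MDA-MB-231 at day 10, where chance gives 10% of arms. At equal list length the counts were 9 and 19 in PC3 at day 10, 6 and 16 at day 1, and 8 and 8 in MDA-MB-231 at day 10, so the low counts of PC3 at day 1 were not kept. Of 170 genes tested on 18q, 105 were lower in PC3 at day 10 and 6 higher, against 13 and 15 in MDA-MB-231. On 20q, 92 of 336 genes were higher in PC3 and 41 lower. The difference between lines on 18q was -0.49 log2 (exact permutation p = 0.025), which did not pass over the arms (adjusted p = 0.171).

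**Figure D5:**
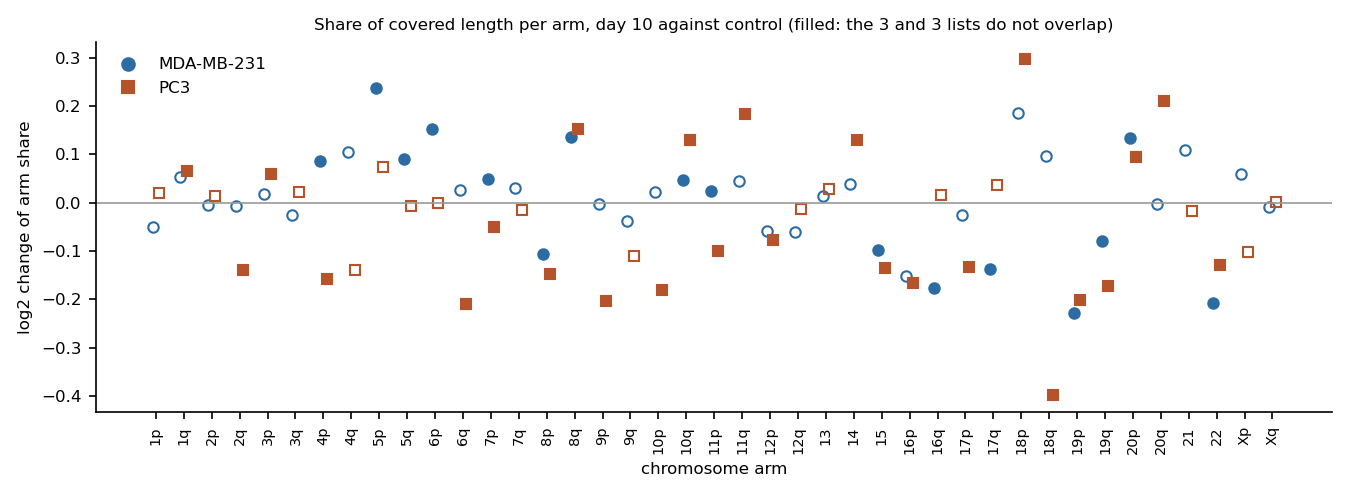
Log2 change in the share of covered length on each of 41 chromosome arms, day 10 against control, for MDA-MB-231 (circles) and PC3 (squares). Filled points are arms whose 3 treated and 3 control lists do not overlap; 18q lies at -0.40 in PC3 and 0.10 in MDA-MB-231.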

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

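Tests of the difference between lines picked out genes whose change in PC3 differed from that in MDA-MB-231; splits of the lists for counts of genes were chosen after the counts were seen, and those for regions before. The limma fit called 884 genes at day 1, 2753 at day 10 and 741 for day 10 against day 1, and at least 529, 1891 and 270 with 1 list left out. At day 10 the largest differences, chosen after their values were seen and given as log2 in PC3 and MDA-MB-231, were TMEM132D (3.46 and 0.30), GFRA1 (2.40 and -0.64), IL17C (2.28 and -0.73), OPCML (4.28 and 1.29) and CYBA (2.35 and -0.63), and in the other direction MACROD2 (-0.07 and 2.77), AGBL4 (0.20 and 2.88), SLC16A9 (-0.47 and 2.20), SFMBT2 (-0.28 and 2.38) and DRGX (0.41 and 3.05). Among 100 splits of the lists, 3 gave as many genes as the real one at day 1 (highest other 1537), 6 at day 10 (4094) and 2 for day 10 against day 1 (1528). In each of the other splits that gave as many, 1 line kept the label of at least 2 of 3 lists of the first group and the other of at most 1, which leaves the effect shared by both lines in the difference, so these counts decide nothing about chance.

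For the mean of both lines, 1 of 100 splits, the real one, gave as many genes in each comparison, with 6400, 9165 and 1528 genes called and 3188, 4094 and 824 as the highest others. A random division of the lists is thus an unlikely source of these counts. Differences in list length or depth that follow the groups are not covered by such splits. Regions gained or lost in both lines gave the same 1 of 100, with 1043, 2719 and 202 regions and 43, 69 and 41 as the highest others. Within a line 10 splits are too few for a share under 0.05. The real counts of genes were 4421, 4650 and 901 in MDA-MB-231 and 2238, 7545 and 1296 in PC3, and the highest others 6, 8, 14, 4, 18 and 74. For regions the real counts were 13012, 16679, 7316, 9143, 22827 and 7051, and the highest others 1688, 1356, 2433, 1773, 1152 and 3834.

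For the excess of gained over lost regions, the test of list length was chosen after the result was seen. With lists of 50000 peaks the ratio of gained to lost regions farthest from 1 was 1.43 over the 4 comparisons with control. Equal list length holds it near 1 by construction, so it decides nothing. The peaks of gained regions had a median area percentile of at most 36.4 in their own lists and those of lost regions of at most 22.0, and since regions absent from 1 group are weak by selection, this rank decides nothing. Splitting of broad peaks was not borne out, since separate regions rose by at least 92.3% of the log2 rise in peaks against control. The mean over lists of the median -log10 p per peak was 5.18, 4.69 and 4.66 in MDA-MB-231 in control, at day 1 and at day 10. In PC3 it was 4.89, 4.57 and 4.44. Among the 50000 highest-area peaks it was 6.42, 5.95 and 5.86, and 6.23, 5.83 and 5.66, with treated and control lists overlapping. By this score treated lists held more but weaker peaks. List length, deeper sequencing and an effect of cisplatin cannot be told apart here, because depth is unknown.

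For the rise of secretory inflammatory genes at day 10, both tests were chosen after the result was seen. The list median lay at the 99.99 percentile or higher in each line among 10000 random lists matched on window length and control level, which speaks against these as the whole cause. Random genes were drawn singly, so the percentile is too extreme where members of the list share peaks. On the mean of both lines the list was called with 50000 peaks per list (adjusted p = 0.00617; from 0.000218 to 0.0291 over its alternatives), while in PC3 alone it was not (adjusted p = 0.0976). With an estimated correlation the list was not called within either line (adjusted p = 0.125 in MDA-MB-231 and 0.0537 in PC3). Endothelial and neuronal genes were called as higher too in PC3 and on the mean, so whether survival of cisplatin changed secretory genes in particular stays open. With an estimated correlation, only the call of neuronal genes on the mean was kept among these. That call was lost with 50000 peaks per list.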

How the results depend on the processing

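The lists hold no read counts, so depth limits every count of peaks, regions and genes here, and falls of genes depend on the scaling. Over the 122 named gene and comparison pairs, 1164 of 1321 values under the alternatives kept direction and side of the threshold, 155 kept direction only and 2 reversed. These were uneven: 58 of 115 kept both with 50000 peaks per list (55 direction only, 2 reversed), 74 of 118 with the upper 50%, 93 of 112 without flanks and 104 of 122 with no scaling, against 122 of 122 with either other pseudocount, no filter or the block. With a list left out, 710 of 732 kept both and 22 direction only. The motif analysis, the exon and intron split, the start-site windows of 1 and 2.5 kb and the 50 kb start-site window were not run, for want of sequence, exons and strand; a gene-end window of 2.5 kb took their place. Where values below differ from the report, the cause was not tested, except that lists of equal length and the upper 50% hold fewer peaks by construction. Only the larger changes in counts are listed below. By construction, counts of regions can only stay or rise with a list left out. The same holds for presence in 3 of 3 against at most 1 of 3 lists.

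With lists of equal length (50000 peaks), the value was 0.00412 for covered length, both lines, day 1 against control (exact permutation p = 0.96), -0.289 for share of peaks at gene ends, both lines, day 1 against control (exact permutation p = 0.345), -0.965 for share of peaks at gene ends, both lines, day 10 against day 1 (exact permutation p = 0.045), -0.0666 for share of covered length in gene-poor windows, both lines, day 1 against control (exact permutation p = 0.78), 0.214 for share of covered length in gene-poor windows, both lines, day 10 against control (exact permutation p = 0.315), -0.28 for FANCI, MDA-MB-231, day 1 against control, log2 change, 0.10 for LMNB1, MDA-MB-231, day 10 against control, log2 change. Regions gained numbered 2880 (MDA-MB-231 day 1 against control), 3843 (MDA-MB-231 day 10 against control), 1672 (MDA-MB-231 day 10 against day 1), 1975 (PC3 day 1 against control), 4199 (PC3 day 10 against control), 1518 (PC3 day 10 against day 1). Regions lost numbered 2323 (MDA-MB-231 day 1 against control), 2696 (MDA-MB-231 day 10 against control), 1644 (MDA-MB-231 day 10 against day 1), 1805 (PC3 day 1 against control), 4221 (PC3 day 10 against control), 1140 (PC3 day 10 against day 1). Regions gained in both lines numbered 169 (day 1 against control), 433 (day 10 against control), 66 (day 10 against day 1). Regions lost in both lines numbered 93 (day 1 against control), 173 (day 10 against control), 9 (day 10 against day 1). Genes higher numbered 648 (MDA-MB-231 day 1 against control), 745 (MDA-MB-231 day 10 against control), 223 (MDA-MB-231 day 10 against day 1), 502 (PC3 day 1 against control), 987 (mean day 1 against control), 1578 (mean day 10 against control), 298 (mean day 10 against day 1). Genes lower numbered 531 (MDA-MB-231 day 1 against control), 553 (MDA-MB-231 day 10 against control), 329 (MDA-MB-231 day 10 against day 1), 491 (PC3 day 1 against control), 3294 (PC3 day 10 against control), 1122 (mean day 1 against control), 2928 (mean day 10 against control), 646 (mean day 10 against day 1). Genes called, difference between lines numbered 460 (day 1 against control). The adjusted p was 0.543 for hypoxia response, MDA-MB-231, day 1 against control, 0.376 for neuronal and neuroendocrine genes, MDA-MB-231, day 1 against control, 0.660 for housekeeping genes, MDA-MB-231, day 1 against control, 0.326 for neuronal and neuroendocrine genes, MDA-MB-231, day 10 against control, 0.488 for neuronal and neuroendocrine genes, PC3, day 1 against control, 0.0976 for secretory inflammatory factors, PC3, day 10 against control, 0.255 for chromatin modifiers, PC3, day 10 against control, 0.252 for neuronal and neuroendocrine genes, PC3, day 10 against control, 0.459 for hypoxia response, mean of both lines, day 1 against control, 0.2003 for neuronal and neuroendocrine genes, mean of both lines, day 1 against control, 0.179 for Fanconi and homologous recombination repair, mean of both lines, day 10 against control, 0.149 for chromatin modifiers, mean of both lines, day 10 against control, 0.176 for neuronal and neuroendocrine genes, mean of both lines, day 10 against control.

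With the replicate block, the value was 0.746 for share of covered length in gene-poor windows, both lines, day 1 against control (exact permutation p = 0.0938). Genes higher numbered 542 (MDA-MB-231 day 10 against day 1). Genes lower numbered 1832 (PC3 day 1 against control). Genes called, difference between lines numbered 1274 (day 10 against day 1). The adjusted p was 0.0542 for secretory inflammatory factors, MDA-MB-231, day 10 against control, 0.0607 for Fanconi and homologous recombination repair, mean of both lines, day 10 against control. These use the replicate number as a block. Same-numbered lists did not all correlate above 0.1 in MDA-MB-231 day 10 and control (0.33, 0.133, 0.0564), PC3 day 1 and control (0.0999, -0.0455, 0.00477) and PC3 day 10 and control (0.0289, 0.253, 0.03), so there pairing was not taken to hold. For MDA-MB-231 day 10 and control it is unsettled, as stated above. The block changed no other call.

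With the upper 50% of each list by area, the value was 0.433 for share of covered length in gene-poor windows, both lines, day 1 against control (exact permutation p = 0.05). Regions gained numbered 5460 (MDA-MB-231 day 1 against control), 6640 (MDA-MB-231 day 10 against control), 1215 (MDA-MB-231 day 10 against day 1), 4275 (PC3 day 1 against control), 10174 (PC3 day 10 against control), 2362 (PC3 day 10 against day 1). Regions lost numbered 267 (MDA-MB-231 day 1 against control), 406 (MDA-MB-231 day 10 against control), 1585 (MDA-MB-231 day 10 against day 1), 1452 (PC3 day 10 against control), 900 (PC3 day 10 against day 1). Regions gained in both lines numbered 438 (day 1 against control), 1121 (day 10 against control), 55 (day 10 against day 1). Regions lost in both lines numbered 6 (day 1 against control), 13 (day 10 against control), 17 (day 10 against day 1). Genes higher numbered 1095 (MDA-MB-231 day 1 against control), 1080 (MDA-MB-231 day 10 against control), 171 (MDA-MB-231 day 10 against day 1), 664 (PC3 day 1 against control), 236 (PC3 day 10 against day 1), 252 (mean day 10 against day 1). Genes lower numbered 1180 (MDA-MB-231 day 1 against control), 801 (MDA-MB-231 day 10 against control), 281 (MDA-MB-231 day 10 against day 1), 590 (PC3 day 1 against control), 2667 (mean day 1 against control), 521 (mean day 10 against day 1). Genes called, difference between lines numbered 551 (day 1 against control).

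With presence in 3 of 3 against at most 1 of 3 lists, regions lost numbered 2355 (MDA-MB-231 day 1 against control), 3564 (MDA-MB-231 day 10 against control), 6903 (MDA-MB-231 day 10 against day 1), 2309 (PC3 day 1 against control), 5819 (PC3 day 10 against control), 6001 (PC3 day 10 against day 1). Regions gained numbered 6564 (MDA-MB-231 day 10 against day 1), 14663 (PC3 day 1 against control), 9809 (PC3 day 10 against day 1).

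With peaks covering at least 50% of the region, regions lost in both lines numbered 75 (day 10 against control).

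With no scaling, genes lower numbered 318 (MDA-MB-231 day 1 against control), 1192 (MDA-MB-231 day 10 against control), 819 (MDA-MB-231 day 10 against day 1), 32 (PC3 day 1 against control), 1186 (PC3 day 10 against control), 608 (PC3 day 10 against day 1), 262 (mean day 1 against control), 2242 (mean day 10 against control), 1751 (mean day 10 against day 1). Genes higher numbered 152 (MDA-MB-231 day 10 against day 1), 2436 (PC3 day 1 against control), 215 (PC3 day 10 against day 1), 3812 (mean day 1 against control), 292 (mean day 10 against day 1). Genes called, difference between lines numbered 405 (day 1 against control), 268 (day 10 against day 1). The adjusted p was 0.121 for hypoxia response, MDA-MB-231, day 1 against control, 0.113 for neuronal and neuroendocrine genes, MDA-MB-231, day 1 against control, 0.113 for housekeeping genes, MDA-MB-231, day 1 against control, 0.112 for neuronal and neuroendocrine genes, PC3, day 1 against control, 0.137 for hypoxia response, mean of both lines, day 1 against control, 0.0669 for neuronal and neuroendocrine genes, mean of both lines, day 1 against control.

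With median-of-ratios scaling, genes lower numbered 956 (MDA-MB-231 day 1 against control), 963 (MDA-MB-231 day 10 against control), 404 (PC3 day 1 against control), 2511 (PC3 day 10 against control), 510 (PC3 day 10 against day 1), 1531 (mean day 1 against control), 2743 (mean day 10 against control), 612 (mean day 10 against day 1). Genes higher numbered 3417 (PC3 day 10 against control), 650 (PC3 day 10 against day 1), 3847 (mean day 10 against control).

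Relative to the chromosome arm, an alternative chosen after seeing the data, genes lower numbered 1438 (MDA-MB-231 day 1 against control), 1283 (MDA-MB-231 day 10 against control), 601 (PC3 day 1 against control), 2609 (PC3 day 10 against control), 387 (PC3 day 10 against day 1), 2174 (mean day 1 against control), 3136 (mean day 10 against control), 495 (mean day 10 against day 1). Genes higher numbered 2987 (PC3 day 10 against control). The adjusted p was 0.0922 for hypoxia response, MDA-MB-231, day 1 against control, 0.0937 for neuronal and neuroendocrine genes, MDA-MB-231, day 1 against control, 0.0922 for housekeeping genes, MDA-MB-231, day 1 against control, 0.0761 for neuronal and neuroendocrine genes, PC3, day 1 against control, 0.0605 for Fanconi and homologous recombination repair, mean of both lines, day 10 against control, 0.0605 for endothelial genes, mean of both lines, day 10 against control.

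With each line fitted alone, genes higher numbered 422 (PC3 day 1 against control), 171 (PC3 day 10 against day 1). Genes lower numbered 323 (PC3 day 1 against control), 228 (PC3 day 10 against day 1).

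With gene bodies without flanks, an alternative chosen after seeing the data, genes lower numbered 629 (mean day 10 against day 1).

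With an estimated inter-gene correlation, the adjusted p was 0.290 for hypoxia response, MDA-MB-231, day 1 against control, 0.290 for neuronal and neuroendocrine genes, MDA-MB-231, day 1 against control, 0.544 for housekeeping genes, MDA-MB-231, day 1 against control, 0.125 for secretory inflammatory factors, MDA-MB-231, day 10 against control, 0.125 for neuronal and neuroendocrine genes, MDA-MB-231, day 10 against control, 0.171 for neuronal and neuroendocrine genes, PC3, day 1 against control, 0.0537 for secretory inflammatory factors, PC3, day 10 against control, 0.197 for chromatin modifiers, PC3, day 10 against control, 0.0537 for neuronal and neuroendocrine genes, PC3, day 10 against control, 0.0537 for endothelial genes, PC3, day 10 against control, 0.158 for hypoxia response, mean of both lines, day 1 against control, 0.113 for neuronal and neuroendocrine genes, mean of both lines, day 1 against control, 0.276 for Fanconi and homologous recombination repair, mean of both lines, day 10 against control, 0.233 for chromatin modifiers, mean of both lines, day 10 against control, 0.384 for HOX genes, mean of both lines, day 10 against control, 0.0921 for endothelial genes, mean of both lines, day 10 against control.

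With each list left out in turn, ranges were as follows. The value ran from -0.376 (without MDA-MB-231 control replicate 1) to -0.179 (without PC3 day 10 replicate 1) for median peak width, both lines, day 10 against control, from 0.646 (without PC3 day 1 replicate 1) to 0.882 (without PC3 control replicate 2) for share of covered length in gene-poor windows, both lines, day 1 against control, from 0.361 (without MDA-MB-231 day 10 replicate 3) to 0.692 (without PC3 day 10 replicate 3) for share of covered length in gene-poor windows, both lines, day 10 against day 1. Regions gained ran from 12356 (without MDA-MB-231 day 1 replicate 3) to 21034 (without MDA-MB-231 day 1 replicate 2) for MDA-MB-231 day 1 against control, from 3552 (without MDA-MB-231 day 1 replicate 2) to 6691 (without MDA-MB-231 day 10 replicate 2) for MDA-MB-231 day 10 against day 1, from 9043 (without PC3 day 1 replicate 1) to 17331 (without PC3 day 1 replicate 2) for PC3 day 1 against control, from 5083 (without PC3 day 1 replicate 2) to 10513 (without PC3 day 10 replicate 3) for PC3 day 10 against day 1. Regions lost ran from 1095 (without MDA-MB-231 day 1 replicate 2) to 1895 (without MDA-MB-231 day 1 replicate 1) for MDA-MB-231 day 1 against control, from 1419 (without MDA-MB-231 day 10 replicate 2) to 3145 (without MDA-MB-231 day 10 replicate 3) for MDA-MB-231 day 10 against control, from 3913 (without MDA-MB-231 day 10 replicate 2) to 8000 (without MDA-MB-231 day 1 replicate 2) for MDA-MB-231 day 10 against day 1, from 1017 (without PC3 day 1 replicate 3) to 1792 (without PC3 day 1 replicate 1) for PC3 day 1 against control, from 2772 (without PC3 day 10 replicate 3) to 4334 (without PC3 day 10 replicate 2) for PC3 day 10 against control, from 2552 (without PC3 day 1 replicate 1) to 3989 (without PC3 day 1 replicate 2) for PC3 day 10 against day 1. Regions gained in both lines ran from 1030 (without MDA-MB-231 day 1 replicate 3) to 1608 (without PC3 day 1 replicate 2) for day 1 against control, from 173 (without MDA-MB-231 day 10 replicate 3) to 294 (without PC3 day 1 replicate 1) for day 10 against day 1. Regions lost in both lines ran from 27 (without MDA-MB-231 day 1 replicate 2) to 54 (without PC3 day 1 replicate 1) for day 1 against control, from 47 (without MDA-MB-231 day 10 replicate 2) to 164 (without MDA-MB-231 day 10 replicate 3) for day 10 against control, from 29 (without MDA-MB-231 day 10 replicate 2) to 64 (without MDA-MB-231 day 10 replicate 3) for day 10 against day 1. Genes lower ran from 1159 (without MDA-MB-231 day 1 replicate 3) to 2112 (without MDA-MB-231 day 1 replicate 2) for MDA-MB-231 day 1 against control, from 1736 (without MDA-MB-231 control replicate 3) to 2195 (without MDA-MB-231 control replicate 1) for MDA-MB-231 day 10 against control, from 225 (without MDA-MB-231 day 1 replicate 3) to 430 (without MDA-MB-231 day 1 replicate 1) for MDA-MB-231 day 10 against day 1, from 374 (without PC3 day 1 replicate 3) to 1144 (without PC3 day 1 replicate 2) for PC3 day 1 against control, from 323 (without PC3 day 1 replicate 2) to 916 (without PC3 day 1 replicate 1) for PC3 day 10 against day 1, from 590 (without PC3 day 1 replicate 2) to 1202 (without PC3 day 10 replicate 3) for mean day 10 against day 1. Genes higher ran from 185 (without MDA-MB-231 day 1 replicate 2) to 403 (without MDA-MB-231 day 1 replicate 1) for MDA-MB-231 day 10 against day 1, from 543 (without PC3 day 1 replicate 3) to 968 (without PC3 control replicate 1) for PC3 day 1 against control, from 185 (without PC3 day 1 replicate 2) to 367 (without PC3 day 1 replicate 1) for PC3 day 10 against day 1. Genes called, difference between lines ran from 529 (without MDA-MB-231 day 1 replicate 3) to 889 (without MDA-MB-231 control replicate 1) for day 1 against control, from 270 (without MDA-MB-231 day 1 replicate 3) to 807 (without PC3 day 10 replicate 1) for day 10 against day 1.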

Other observations

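For 18q, the lowest of 41 arms in PC3 at day 10, both tests were chosen after the result was seen. Weak peaks added in gene-poor arms were not borne out, since 18q lay -0.38 log2 from the line of arm change on genes per Mb. Gene-end peaks and other peaks on 18q both fell, the smaller fall being -0.40 log2. Fewer copies of 18q in PC3 survivors are a candidate explanation, which the lists cannot settle because they hold no read counts.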
